A study of Mus musculus and Homo sapiens with 43 samples.

How the data were processed

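The series holds 43 poly-A RNA libraries, 38 from mouse cells and 5 from human HEK293 cells, read as single 51-base reads. The mouse libraries form 11 groups: fibroblasts from embryos of the C57BL/6 strain, ES cells of the 129/Ola strain, OSKM, C2, C3 and C4 iPS cells, their 4 early counterparts and Empty early cells. Fibroblasts, ES cells and OSKM, C2 and C4 iPS cells have 4 libraries each, and the other groups have 3. The labels give 100 nM tamoxifen for all iPS and early groups and none for fibroblasts and ES cells. Contrasts of iPS or early cells with fibroblasts or ES cells therefore also hold this treatment. The replicate labels do not say whether replicates came from separate cultures. Each HEK293 condition has 1 library: a mock transfection, and constructs with 2 or 3 zinc fingers of the EGR1 DNA-binding domain, a nuclear localization signal and VP64, without or with a segment that the labels call ID.

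The FPKM values were made by the authors before deposit: per the submitters' processing notes, reads passed through CASAVA 1.8.2, TopHat2 (2.1.1 for mouse, 2.0.6 for human), Cufflinks (2.2.1 for mouse, 2.1.0 for human) and Cuffdiff, whose version is not given. The submitters' processing notes name the builds mm10 and hg19. In the mouse files the authors combined the libraries of a group into 1 FPKM value, so replicate values could not be used here. Read depth is unknown because no counts were among the files. The p-values and q-values were computed by the authors with Cuffdiff, as deposited, for 55 pairs of mouse groups and 10 pairs of HEK293 libraries. The deposited mouse q-value equalled a Benjamini-Hochberg adjustment over all 946747 completed tests of all 55 pairs to within 5.28e-07, with a smallest p-value of 5e-05 and a largest p-value of 0.01355 among those called. The 4 columns of values in the 2 comparison tables, which hold 1 value per mouse group or HEK293 library and none per mouse replicate, were not used, and the group files were read instead.

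Differences are of log2(FPKM + 1), with no further scaling between groups. A mouse gene counted as changed when the deposited q-value was below 0.05. Of 39437 mouse loci, 23368 carried a gene symbol and were counted. The 16069 unnamed loci had a median width of 69 bases and made up 53.5% to 98.9% of the FPKM sum of a group, so they were left out of the counts. The named genes are the 10 largest differences in each direction with at least 5 FPKM in the higher group, or for families of contrasts those called in all, and members of the lists. Rows with an isolated value, above 2000 FPKM in 1 group and more than 20 times the next highest, were skipped in naming for 37 loci. That rule was chosen after the data were seen. Rows that peaked in several groups, such as Hyls1, were skipped in the same way.

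Lists were written before the data were examined. The mouse lists are pluripotency, reprogramming factors, fibroblast and mesenchymal, epithelial, contractile, skeletal muscle, macrophage, endothelial, neural, mesendoderm, trophectoderm, primed epiblast, 2-cell-like, cell cycle, senescence and p53, interferon response, inflammatory, DNA methylation, imprinted, glycolysis, sex-linked and ubiquitous genes. The human lists are the EGR family, EGR1 targets, immediate early, interferon, heat shock and unfolded protein, p53, cell cycle, neuronal, pluripotency, kidney epithelial, cholesterol and ubiquitous genes. A member counted as measured at 1 FPKM or more in either group. Counts of called members were tested with Fisher's exact test against all other tested genes, and the 868 tests were adjusted together. Medians were placed among 10000 random lists drawn from 20 expression bins. Lists adjusted over the list alone used a Benjamini-Hochberg adjustment of the deposited p-values of the members.

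The stage contrast used limma on 8 group values with cocktail as a block and called genes at an adjusted p-value below 0.05. Positions on the fibroblast to ES axis are projections over 13230 genes, with intervals from 1000 bootstrap draws of genes. Overlaps between contrasts with a shared group were compared with 20 draws of unchanged genes, simulated from the variances that the deposited p-values imply for 9952 genes. In HEK293 cells a gene differed when it moved by at least 1 on the log2 scale with at least 5 FPKM in the higher library. Of 56998 human loci, 54032 were used, after rows with several symbols, 27 symbols turned into dates and 159 rows without a completed estimate were left out. All 2252 human loci on chromosome X are listed at 0 in every library, against 52.4% of autosomal loci above 0, so genes of that chromosome were not read.

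The functions were tested on simulated data before use. The stage fit recovered 18% of 50 genes changed by 1 on the log2 scale, 52% at 2, 92% at 4 and 92% at 6, and 12 of 139 calls were wrong. Unchanged lists fell in the outer 5% of random lists in 6.67% of 300 cases and passed the Fisher test in 2.67%, and raised lists were found in 99%. The axis function placed a group made at 30% at 30%.

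The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Alternatives tried were a correction within each contrast, a q-value of 0.01, a size limit of 1, a filter at 1 FPKM, inclusion of unnamed loci, removal of isolated loci, a pseudocount of 0.1, quantile normalization and leaving out cocktails. A fit per replicate was left out because each group entered as 1 value. Results for a few genes are not reported here.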

Results

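Pou5f1, which encodes the transcription factor Oct4, stood at 0.789 FPKM in mouse embryonic fibroblasts and 665 FPKM in embryonic stem (ES) cells. Nanog, a homeobox regulator of pluripotency, rose from 1.09 to 345 FPKM. Zfp42, a zinc finger gene used as a marker of undifferentiated cells, rose from 0.2 to 320 FPKM, and L1td1, an RNA-binding protein gene of stem cells, rose from 0.343 to 304 FPKM. The fibroblast collagens went the other way: Col1a1 fell from 4937 to 1.52 FPKM and Col3a1 from 518 to 0.116 FPKM. Acta2, the smooth muscle actin gene, fell from 1591 to 1.00 FPKM, and Tagln, which encodes an actin-binding protein of contractile cells, fell from 983 to 1.81 FPKM.

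These 2 groups are the reference ends for 9 further mouse groups: 4 kinds of induced pluripotent stem (iPS) cells and 5 groups of early cells, all started from fibroblasts. OSKM cells received Oct4, Sox2, Klf4 and c-Myc. In C2, C3 and C4 cells Oct4 was replaced by 3 zinc finger artificial transcription factors (ZFATFs), and Empty cells received no replacement. All values of groups are the authors' deposited group FPKM. By the authors' deposited table, 6355 genes passed a q-value of 0.05 between ES cells and fibroblasts, 3192 higher and 3163 lower in ES cells. Each group entered with 1 value and no values of single replicates were available here, so the test could not be repeated here.

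Named lists of genes, fixed before the data were examined, placed this contrast by cell function. Where a list has 1 count here or in later contrasts, it was the same when adjusted over the list alone. Of the 30 pluripotency genes, 19 were called higher in ES cells in the authors' deposited table and 0 lower, with the same 19 when adjusted over the list alone. Their median log2 difference was 5.95 (adjusted Fisher p 0.00047). Dppa5a, an RNA-binding protein gene of stem cells, was not called in the authors' deposited table although its values were 0.7 and 2383 FPKM. Of the 30 fibroblast and mesenchymal genes, 23 were lower in ES cells in the authors' deposited table (24 when adjusted over the list alone), with a median of -5.68 and an adjusted Fisher p of 4.1e-07. Thy1, a surface protein of fibroblasts, fell from 133 to 6.45 FPKM, and Twist2, a mesenchymal regulator, fell from 32 FPKM to a row listed at 0.

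Most cell cycle and glycolysis genes were also higher in ES cells. Mcm5, a subunit of the replicative helicase, rose from 12.9 to 153 FPKM, and Ccnb1, the cyclin of mitotic entry, rose from 13.3 to 93.1 FPKM. Per the calls of the authors' deposited table, 21 of 22 cell cycle genes were higher (22 adjusted over the list alone; median 2.5; adjusted Fisher p 1.3e-09). Slc2a1, a glucose transporter, rose from 50.9 to 373 FPKM, and in the authors' deposited table, 14 of 16 glycolysis genes were higher (15 adjusted over the list alone; median 1.39; adjusted Fisher p 1.6e-05). Of 8 measured genes of the 2-cell-like state, 7 were higher in the authors' deposited table (7 adjusted over the list alone; median 1.6; adjusted Fisher p 0.006), among them Zscan4f, a telomere-related zinc finger gene, listed at 0 in fibroblasts and at 3.37 FPKM in ES cells. Cdkn1a, which encodes the p21 cell cycle inhibitor, fell from 117 to 17.1 FPKM. In the authors' deposited table, 11 of 16 senescence and p53 genes were lower and 4 higher in ES cells (the same when adjusted over the list alone; median -1.8; adjusted Fisher p for lower 0.0051).

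Lists of other lineages passed no test in this contrast. By the authors' deposited table the counts higher and lower were 1 and 0 of 6 skeletal muscle genes, 0 and 0 of 6 macrophage genes and 2 and 0 of 5 endothelial genes, and each count was the same when adjusted over the list alone. Primed epiblast genes gave 5 and 0 of 9 in the authors' deposited table, sex-linked genes 0 and 2 of 5, and both were unchanged when adjusted over the list alone. The 17 ubiquitous genes gave 7 and 4 in the authors' deposited table (11 and 4 adjusted over the list alone), with a median of 0.55. Otx2, a homeobox gene of the primed epiblast, stood at 0.0109 FPKM in fibroblasts and 475 FPKM in ES cells without being called.

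Zfp42 rose from 0.2 FPKM in fibroblasts to 349 FPKM in OSKM, 229 in C2, 205 in C3 and 236 in C4 iPS cells. Esrrb, an orphan nuclear receptor of naive stem cells, rose from 0.138 FPKM to 163, 178, 151 and 194 FPKM in the same order. Sall4, a zinc finger partner of Oct4, rose from 0.195 to 121 FPKM in C3 and 191 FPKM in C4 iPS cells. Dppa4, a chromatin protein gene of early embryos, rose from 0.526 to 178 FPKM in C4 and 208 FPKM in C2 iPS cells. Apoe, a lipid carrier gene, rose from 2.76 to 837 FPKM in OSKM and 1258 FPKM in C4 iPS cells, and Upp1, a uridine phosphorylase gene, rose from 2.07 to 362 FPKM in C2 iPS cells.

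Col5a2, a fibrillar collagen gene, fell from 1234 FPKM in fibroblasts to between 1.15 FPKM in OSKM and 1.46 FPKM in C3 iPS cells. Thbs1, a secreted glycoprotein of the matrix, fell from 3134 to between 2.84 FPKM in C2 and 5.78 FPKM in C4 iPS cells. Lox, which crosslinks collagen, fell from 981 to 0.467 FPKM in C3 iPS cells, and Bgn, a matrix proteoglycan gene, fell from 739 to 0.683 FPKM in the same cells. Il1rl1, a cytokine receptor gene, fell from 239.7 to 0.0710 FPKM in C3 iPS cells. Col1a1 fell to 3.20 FPKM in C2 but only to 26.0 FPKM in C3 iPS cells.

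The authors' deposited table called 6261 genes in OSKM iPS cells against fibroblasts (3216 higher and 3045 lower). It called 6288 in C2 (3337 and 2951), 6163 in C3 (3085 and 3078) and 6289 in C4 iPS cells (3299 and 2990), again per the authors' deposited table. Of 12051 genes tested in each contrast in the authors' deposited table, 2499 were higher and 2271 lower in all 4 kinds of iPS cells. Independent calls would give 54.2 and 47.3, and simulated unchanged genes with the shared fibroblast group gave 2.79 and 3.03. Part of the excess may still come from the shared fibroblasts, because the control could not be split with 1 value per group. With ES cells added, 2167 were higher and 2082 lower in all 5 contrasts of 11940 genes tested in the authors' deposited table (independent 13.1 and 12.9; simulated 1.44 and 1.56).

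Per the calls of the authors' deposited table, 19 of 30 pluripotency genes were higher in OSKM, C2 and C4 iPS cells and 17 in C3 (19 in each when adjusted over the list alone), with medians of 5.93, 6.22, 6.11 and 5.77. Nanog was not called in C3 iPS cells in the authors' deposited table (152 FPKM, q 0.0651). In the authors' deposited table the fibroblast genes were lower for 19 of 30 in OSKM, 21 in C2, 24 in C3 and 24 in C4, with adjusted Fisher p of 0.00037, 6.8e-06, 3.2e-08 and 2.2e-08. Adjusted over the list alone the fibroblast counts were 20 in OSKM and 23 in C2. Contractile genes were lower for 9 of 12 in OSKM (9 adjusted over the list alone) and 10 of 12 in C2 in the authors' deposited table, with medians of -5.37 and -5.07. Cell cycle genes were higher for 21 of 22 in OSKM, C2 and C4 and 20 in C3 (21 adjusted over the list alone) in the authors' deposited table. Dnmt3b, a de novo DNA methyltransferase gene, rose from 0.45 to between 63.8 FPKM in OSKM and 82.1 FPKM in C3, and 8 of 10 DNA methylation genes were higher in each kind of iPS cell in the authors' deposited table (8 adjusted over the list alone in OSKM; adjusted Fisher p 0.007).

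**Figure D1:**
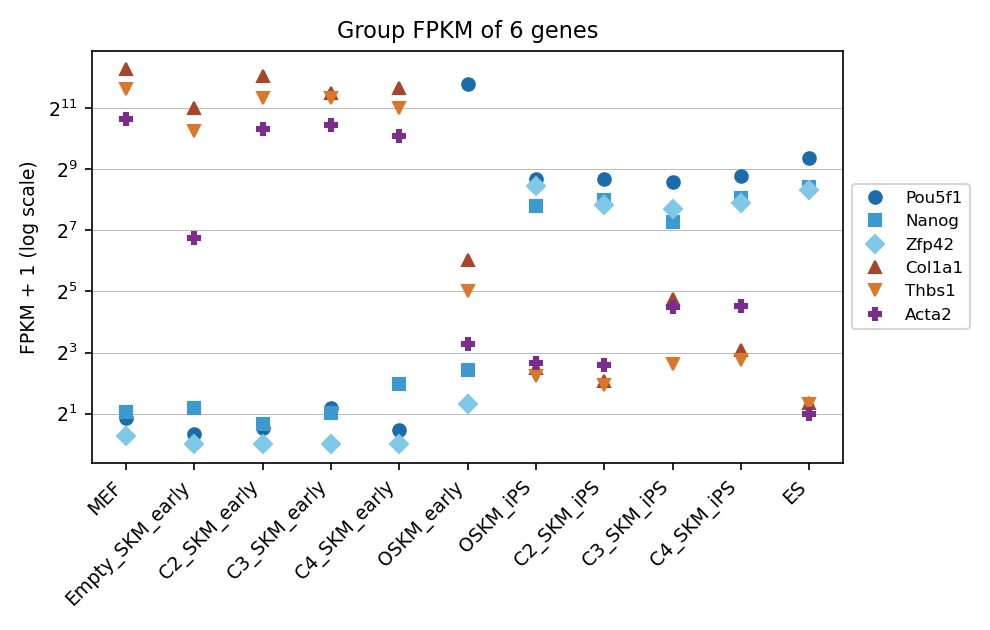
FPKM + 1 of 6 genes in the 11 mouse groups on a log axis, 1 symbol per group. Pou5f1 reached 3569 FPKM in OSKM early cells, where Zfp42 stood at 1.49 FPKM. Oct4 was delivered to these cells, and reads of the construct were not separated from those of the endogenous gene.

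Pou5f1 was lower in every kind of iPS cell than in ES cells, at 411 FPKM in OSKM, 408 in C2, 382 in C3 and 437 in C4 against 665 FPKM. Hprt, a purine salvage gene, stood at 0.957 FPKM in ES cells and at 175, 157, 134 and 170.0 FPKM in OSKM, C2, C3 and C4 iPS cells. Chac1, a glutathione-degrading enzyme induced by amino acid stress, was 5.95 FPKM in ES cells and 84.1 FPKM in OSKM iPS cells. Trib3, a pseudokinase gene of the same stress response, was 11.99 against 111 FPKM, and Stc2, a secreted stress-response glycoprotein, was 4.56 against 28.9 FPKM in these groups. Mest, a paternally expressed imprinted gene, was 3.01 FPKM in ES cells and 34.8 FPKM in OSKM iPS cells. Cebpb, a basic leucine zipper gene, was 1.72 FPKM in ES cells and 62.1 FPKM in C4 iPS cells, and Olig1, a helix-loop-helix gene of glial precursors, was 0.679 against 11.2 FPKM in C2.

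Ldha, which makes lactate from pyruvate, was 716 FPKM in ES cells and 166 FPKM in C4 iPS cells, and Slc2a1 was 373 against 104.6 FPKM. Tpi1, a glycolytic isomerase gene, was 227 FPKM in ES cells and 59.3 FPKM in OSKM iPS cells. Mid1, a ubiquitin ligase gene on the X chromosome, was 238 FPKM in ES cells and 5.67 FPKM in C2 iPS cells. Trp53i11, a p53-induced gene, was 51.7 against 4.74 FPKM in OSKM, Prmt8, a brain arginine methyltransferase gene, was 16.8 against 0.494 FPKM in C4, and Snhg3, a small nucleolar RNA host gene, was 161 against 15.4 FPKM in C3. Slc16a3, which exports lactate, was 64.8 FPKM in ES cells and 7.47 FPKM in C4 iPS cells.

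Against ES cells the authors' deposited table called 1988 genes in OSKM iPS cells (1049 higher and 939 lower), 2061 in C2 (1222 and 839), 1834 in C3 (994 and 840) and 2374 in C4 (1469 and 905). With a q-value of 0.01 instead, these counts from the authors' deposited table were 1178, 1220, 1040 and 1452. Of 11187 genes tested in all 4 contrasts in the authors' deposited table, 474 were higher and 321 lower in every kind of iPS cell. Independent calls would give 1.13 and 0.428, simulated unchanged genes gave 1.52 and 0.843, and part of the excess may come from the shared ES group. The ES cells are of another mouse strain than the iPS cells, and the labels give tamoxifen only for the iPS cells. Strain, treatment and cell type were not separable in this contrast.

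Glycolysis genes were the list with the lowest p-values against ES cells. By the authors' deposited table, 13 of 16 were lower in OSKM, 11 in C2, 10 in C3 (12 adjusted over the list alone) and 12 in C4 iPS cells, and 0 were higher. Their medians were -1.22, -0.81, -0.76 and -1.16, with adjusted Fisher p of 1.2e-09, 6.9e-08, 1.3e-06 and 8.5e-09. H19, a maternally expressed imprinted RNA, was 1.51 FPKM in ES cells and 46.8 FPKM in C3 iPS cells, and Peg3, a paternally expressed zinc finger gene, was 3.24 against 8.05 FPKM in C4. Per the calls of the authors' deposited table imprinted genes were higher than in ES cells for 9 of 14 in C4 (median 1.09; adjusted Fisher p 0.00037), 6 of 14 in C3 (7 adjusted over the list alone; 0.0083), 5 of 13 in OSKM (6 adjusted over the list alone; 0.029) and 2 of 14 in C2. In the authors' deposited table, 3 imprinted genes were lower in each of OSKM, C2 and C3 and 2 in C4. Cdkn1c, an imprinted cell cycle inhibitor gene, fell from 15.3 FPKM in ES cells to 2.67 FPKM in OSKM, 1.57 FPKM in C2, 2.91 FPKM in C3 and 2.56 FPKM in C4, and Phlda2, its imprinted neighbour, fell from 41.5 to 9.38, 3.58, 6.03 and 4.86 FPKM.

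The pluripotency list was split against ES cells. Sall4, Klf5, a Krüppel-like factor gene of self-renewal, and Tbx3, a T-box gene of naive stem cells, were higher in all 4 kinds of iPS cells. Klf5 was 97.8 FPKM in ES cells and 227 FPKM in C4, and Tbx3 was 47.6 against 137 FPKM. Dppa5a was lower in all 4, at 2383 FPKM in ES cells and 1022 FPKM in OSKM iPS cells. In the authors' deposited table the counts higher and lower were 7 and 4 in OSKM (9 and 4 adjusted over the list alone), 7 and 4 in C2, 8 and 3 in C4, and 3 and 10 in C3, where the adjusted Fisher p for lower was 0.00087. Gata4, an endoderm regulator, was 1.57 FPKM in ES cells and 5.08 FPKM in C3, and 3 of 5 mesendoderm genes were higher in C3 in the authors' deposited table (adjusted Fisher p 0.024). Gadd45a, a DNA damage gene, was higher in all 4 kinds of iPS cells (34.5 FPKM in ES cells, 93.3 in C2), and Cdkn1a was lower in all 4 (17.1 FPKM in ES cells, 5.59 in OSKM).

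Acsf2, an acyl-CoA synthetase gene, was 5.96 FPKM in OSKM iPS cells and 564, 2059 and 836 FPKM in C2, C3 and C4 iPS cells. Clu, a secreted chaperone gene, was 9.17 FPKM in OSKM iPS cells and 32.1, 96.7 and 85.2 FPKM in the others. Lama1, a laminin chain of early basement membranes, was 10.2 against 26.2, 67.4 and 80.6 FPKM, and Col4a2, the collagen partner of the same membranes, was 8.94 against 23.0, 77.6 and 93.7 FPKM. Fkbp6, a germ cell co-chaperone gene, was 26.5 against 75.2, 80.03 and 69.1 FPKM, and Rhox9, an X-linked homeobox gene, was 4.32 against 16.8, 17.9 and 15.0 FPKM. Tinagl1, a matrix glycoprotein gene, was 2.43 FPKM in OSKM iPS cells and 19.3 FPKM in C3, Htra1, a secreted serine protease gene, was 4.80 against 20.5 FPKM, and Anxa2, a membrane-binding annexin gene, was 9.76 against 30.7 FPKM.

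Sestd1, a phospholipid-binding protein gene, was 126 FPKM in OSKM iPS cells and 16.6, 8.81 and 15.7 FPKM in C2, C3 and C4. Gli1, a Hedgehog pathway target, was 21.3 against 7.22, 6.16 and 7.75 FPKM, and Crmp1, a cytoskeletal protein of growing axons, was 15.4 against 3.50, 7.48 and 6.01 FPKM. The sterol synthesis genes Sc4mol, a methyl oxidase, and Idi1, an isomerase, were 34.3 and 20.03 FPKM in OSKM iPS cells and 14.7 and 3.59 FPKM in C3. Klf4, 1 of the delivered factors, was higher in all 3 kinds than in OSKM iPS cells (71.7 FPKM against 106, 154 and 113), and Zfp42 was lower in all 3.

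The authors' deposited table called 511 genes between C2 and OSKM iPS cells (306 higher and 205 lower in C2), 757 for C3 (395 and 362) and 556 for C4 (381 and 175). These counts depended on how the correction was scoped: over the genes of each contrast alone, the p-values of the authors' deposited table gave 163, 248 and 182. Of 10910 genes tested in all 3 contrasts in the authors' deposited table, 68 were higher and 64 lower in all 3 kinds than in OSKM iPS cells. Independent calls would give 0.303 and 0.109 and simulated unchanged genes 2.80 and 2.85, and part of the excess may come from the shared OSKM group.

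Gata6, a primitive endoderm regulator, was 0.706 FPKM in OSKM iPS cells and 3.85 FPKM in C3 and 4.02 FPKM in C4, and Sox7, an endoderm and endothelial regulator, was 0.772 against 2.52 and 2.19 FPKM. By the authors' deposited table, 3 of 5 mesendoderm genes were higher in C3 (adjusted Fisher p 0.00093) and 3 of 5 in C4 (0.00089), whereas Eomes, another member, was 1.19 FPKM in OSKM, 0.536 FPKM in C3 and 1.13 FPKM in C4. Fibroblast genes were higher for 5 of 17 in C3 in the authors' deposited table (adjusted Fisher p 0.0021), and contractile genes for 4 of 8 in C4 (0.0015). Col4a1, a basement membrane collagen gene, reached 117 FPKM in C3. Of 30 pluripotency genes, 7 were lower in C3 than in OSKM iPS cells in the authors' deposited table (adjusted Fisher p 0.00089; median -0.28), among them Prdm14, a germline and stem cell regulator, at 2.39 against 5.07 FPKM. C2 iPS cells passed no list test against OSKM, with 2 of 30 pluripotency genes higher and 1 lower in the authors' deposited table (2 and 0 adjusted over the list alone). Airn, an imprinted antisense RNA, was 18.7 FPKM in C4 and 0.0276 FPKM in OSKM iPS cells, and Ddx3y, a Y-linked helicase gene, was 4.09 FPKM in C2 and 33.4 FPKM in OSKM iPS cells.

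On the line from fibroblasts at 0% to ES cells at 100%, the iPS groups lay between 84.1% in C4 and 86.9% in C2. C3 iPS cells were at 85.3% and OSKM iPS cells at 84.6%, and the gene bootstrap intervals of all 4 overlapped (81.4% to 86.6% for C4, 84.2% to 89.3% for C2). OSKM early cells were at 50.2% (47.9% to 52.3%). Empty early cells were at 16.7%, C3 early cells at 16.5%, C4 early cells at 17.3% and C2 early cells at 14.1% (12.6% to 15.6%). The positions used 13230 genes, and the intervals come from resampling genes, which are not independent. Differences between groups on this axis were not tested.

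**Figure D2:**
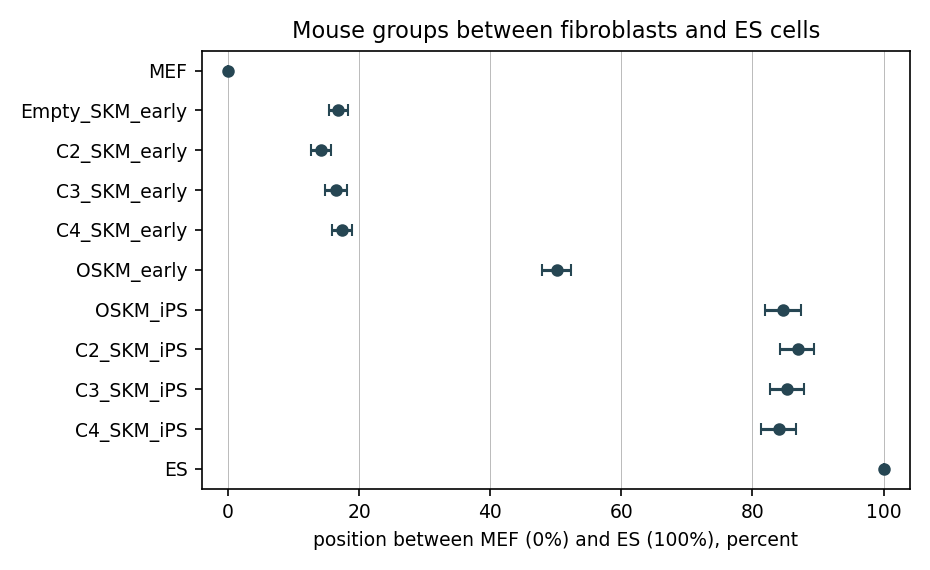
Position in percent of the 11 mouse groups between fibroblasts and ES cells, with 95% gene bootstrap bars. OSKM early cells at 50.2% stand apart from the other 4 early groups, all at 17.3% or less.

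Empty early cells received Sox2, Klf4 and c-Myc without Oct4 or ZFATFs. Their puromycin resistance row, PURO, stood at 1764 FPKM. Unlike the fibroblasts, they are labelled with tamoxifen, so its effect was not separated in this contrast. Aldh3a1, a detoxifying dehydrogenase of epithelia, rose from 0.328 FPKM in fibroblasts to 262 FPKM. Mal, a membrane protein of lipid rafts, rose from 0.186 to 154 FPKM, and Prelp, a leucine-rich repeat matrix protein, rose from 19.7 to 897 FPKM. C3, the central complement gene, rose from 0.714 to 197 FPKM, and Lbp, a lipopolysaccharide-binding acute-phase gene, rose from 0.25 to 51.4 FPKM. Krt14, a basal keratin gene, rose from a row listed at 0 to 60.8 FPKM, whereas Krt19, another keratin gene, fell from 20.8 to 7.31 FPKM. Penk, which encodes an opioid precursor, fell from 251 to 6.15 FPKM, Thy1 fell from 133 to 0.996 FPKM, and Ptn, a heparin-binding growth factor gene, fell from 85.5 to 0.666 FPKM. Adm, a vasodilator peptide gene, fell from 234 to 3.04 FPKM, and Cck, a gut and brain peptide gene, fell from 98.1 FPKM to a row listed at 0.

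The authors' deposited table called 2920 genes between Empty early cells and fibroblasts, 1479 higher and 1441 lower. Sox2 rose from 0.562 to 32.4 FPKM, Klf4 from 40 to 121 FPKM and Myc from 28.3 to 234 FPKM, but these 3 were delivered, and reads of the constructs were not separated from those of the endogenous genes. Per the calls of the authors' deposited table, 12 of 30 fibroblast genes were lower (15 adjusted over the list alone; median -0.89; adjusted Fisher p 0.0024) and 6 of 12 contractile genes (median -3.74; 0.012). Cell cycle genes were higher for 9 of 22 (10 adjusted over the list alone; adjusted Fisher p 0.011) in the authors' deposited table. Of 14 interferon response genes, 7 were lower in the authors' deposited table (8 adjusted over the list alone; adjusted Fisher p 0.0088). Imprinted genes were lower for 8 of 14 in the authors' deposited table (median -2.47; adjusted Fisher p 0.00093), with Mest at 28.6 and 0.713 FPKM.

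Fbn1, which encodes the microfibril protein fibrillin, fell from 275 FPKM in Empty to 3.96 FPKM in OSKM early cells, Bgn from 1139 to 16.1 FPKM and Prelp from 897 to 1.13 FPKM. Sod3, an extracellular superoxide dismutase gene, fell from 540.3 to 0.969 FPKM, Saa3, an acute-phase amyloid gene, fell from 665 to 2.57 FPKM, and Col2a1, a cartilage collagen gene, fell from 213 to 0.988 FPKM. L1td1 rose from a row listed at 0 to 225 FPKM, and Tdgf1, a Nodal co-receptor gene, from a row listed at 0 to 86.7 FPKM. Rhox5, an X-linked homeobox gene of germ and stem cells, rose from a row listed at 0 to 158 FPKM, and Peg3 rose from 0.224 to 120.4 FPKM. Eps8l2, an actin-binding protein of epithelial edges, rose from 0.941 to 491 FPKM, and Krt19, an epithelial keratin gene, rose from 7.31 to 316 FPKM. Cdh1, the epithelial cadherin gene, rose from 0.533 to 23.0 FPKM.

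The authors' deposited table called 3412 genes between OSKM and Empty early cells, 1570 higher and 1842 lower in OSKM. Of 24 pluripotency genes, 10 were higher and 1 lower (12 and 2 adjusted over the list alone; median 2.43; adjusted Fisher p 0.00097) in the authors' deposited table. Pou5f1 was not called in the authors' deposited table (0.25 and 3569 FPKM, q 0.384), and neither was Nanog (1.28 and 4.38 FPKM, q 0.489). Oct4 was delivered to OSKM cells, and reads of the construct were not separated from those of endogenous Pou5f1. Fibroblast genes were lower for 20 of 28 (20 adjusted over the list alone; median -3.66; adjusted Fisher p 7.6e-09) in the authors' deposited table, and inflammatory genes for 9 of 14 (median -4.32; 0.00059). Epithelial genes were higher for 7 of 17 (8 adjusted over the list alone; median 3.38; adjusted Fisher p 0.019) in the authors' deposited table, and trophectoderm genes for 4 of 5 (median 1.34; 0.015). Tet1, a DNA demethylation enzyme, rose from 0.0999 to 15.2 FPKM, and DNA methylation genes were higher for 7 of 10 (8 adjusted over the list alone; adjusted Fisher p 0.00054) in the authors' deposited table. Glycolysis genes were higher for 10 of 16 (12 adjusted over the list alone; median 0.77; adjusted Fisher p 0.00025) in the authors' deposited table. Xist, the X-inactivation RNA, was 0.0626 FPKM in Empty and 47 FPKM in OSKM early cells, and Ddx3y was 24.4 against 2.3 FPKM.

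Acta2 was 106 FPKM in Empty early cells and 1277, 1401 and 1091 FPKM in C2, C3 and C4 early cells. Fibroblasts, the starting cells, had a higher Acta2 value than any of these groups. A gain in C2, C3 and C4 was not separated from a loss in Empty. Tpm2, a tropomyosin gene, was 84.4 FPKM in Empty against 461, 751 and 318 FPKM. Myl9, a myosin light chain gene, was 3.83 against 27.6, 19.3 and 20.4 FPKM. Fhl1, a LIM-domain gene of muscle, rose from 10.4 to 121, 139 and 66.8 FPKM, Zyx, a focal adhesion gene, from 105.2 to 383, 336 and 396 FPKM, and Has2, which makes hyaluronan, from 2.58 to 10.5, 26.0 and 15.7 FPKM. Filip1l, a filamin-interacting protein gene, rose from 7.70 to 41.9, 29.6 and 39.4 FPKM, Aldh1l2, a mitochondrial folate enzyme gene, from 1.75 to 11.1, 9.22 and 19.8 FPKM, and Acta1, the skeletal actin gene, from 1.59 to 8.02, 19.4 and 31.0 FPKM.

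Agt, the angiotensin precursor gene, fell from 7.44 FPKM in Empty to rows listed at 0 in all 3, and so did Myoz1, a sarcomere protein gene, from 6.195 FPKM. Lgr5, a Wnt pathway receptor gene, fell from 11.0 to 0.757, 0.746 and 0.393 FPKM, and Grem1, a BMP antagonist gene, fell from 43.8 to 4.78, 6.43 and 6.03 FPKM. Ltbp2, a latent TGF-beta binding protein gene, fell from 94.8 to 9.50, 13.4 and 15.2 FPKM, Mmp2, a matrix metalloprotease gene, from 289.6 to 68.1, 14.4 and 27.9 FPKM, and Thbd, the thrombomodulin gene, from 60.1 to 8.17, 15.3 and 8.16 FPKM. Serpina3n, an acute-phase protease inhibitor gene, fell from 16.8 to 0.977, 1.14 and 2.62 FPKM. Pou5f1 stayed low, at 0.25 FPKM in Empty and 0.454, 1.25 and 0.376 FPKM in C2, C3 and C4.

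The authors' deposited table called 885 genes in C2 early cells against Empty (451 higher and 434 lower), 1026 in C3 (434 and 592) and 928 in C4 (417 and 511). Corrected over the genes of each contrast alone, the p-values of the authors' deposited table gave 485, 611 and 592. Of 10895 genes tested in all 3 contrasts in the authors' deposited table, 112 were higher and 124 lower in all 3. Independent calls would give 0.513 and 1.10 and simulated unchanged genes 3.01 and 2.19, and part of the excess may come from the shared Empty group. Of 10 contractile genes, 4 were higher in C2, 5 in C3 and 5 in C4 in the authors' deposited table (medians 2.41, 1.84 and 1.81; adjusted Fisher p 0.006, 0.00054 and 0.00047). The median of this list was lower in Empty early cells than in fibroblasts, so a gain was not separated from a loss in Empty. Glycolysis genes were higher for 2 of 16 in C2 (1 adjusted over the list alone), 13 in C3 (14 adjusted over the list alone; adjusted Fisher p 1.9e-13) and 6 in C4 (9 adjusted over the list alone; 0.00047) in the authors' deposited table, with Ldha at 558 FPKM in Empty and 1188 FPKM in C3.

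Col1a2, the partner chain of type I collagen, fell from 1270 FPKM in Empty to 42.5 FPKM in C3 and 96.3 FPKM in C4 early cells and stood at 1377 FPKM in C2. Mgp, a calcification inhibitor gene, fell from 220 to 8.41 FPKM in C3 and 9.48 FPKM in C4, and Igfbp4, an insulin-like growth factor binding protein gene, fell from 158 to 4.39 FPKM in C3. In the authors' deposited table the fibroblast counts higher and lower were 5 and 2 of 27 in C2 (adjusted Fisher p for higher 0.037), 3 and 8 of 28 in C3 (4 and 8 adjusted over the list alone; for lower 0.00096) and 2 and 7 of 28 in C4 (for lower 0.0034). Loxl2, a collagen crosslinking gene, rose from 2.05 to 53.6 FPKM in C2, and Cxcl5, a neutrophil chemokine gene, from 12.02 to 160 FPKM. Inflammatory genes gave 4 higher and 1 lower of 14 in C2 in the authors' deposited table (4 and 3 adjusted over the list alone; adjusted Fisher p for higher 0.02), although their median was -0.09, opposite in sign to the test. In C4 the authors' deposited table had 5 higher and 4 lower of 15 inflammatory genes (6 and 4 adjusted over the list alone; adjusted Fisher p 0.002 and 0.03). Senescence and p53 genes were higher for 4, 6 and 6 of 16 in the authors' deposited table (4, 7 and 6 adjusted over the list alone; adjusted Fisher p 0.03, 0.00054 and 0.00047). Tubb3, a neuronal tubulin gene, rose from 27.3 to 62.1 FPKM in C4, where 3 of 5 neural genes were higher in the authors' deposited table (adjusted Fisher p 0.0064).

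Prelp was 1.13 FPKM in OSKM early cells and 422, 502 and 478 FPKM in C2, C3 and C4 early cells. Pi15, a secreted protease inhibitor gene, was 0.458 against 158, 103 and 113 FPKM, and Fbn1 was 3.96 against 234, 234 and 295 FPKM. Epb4.1l3, a membrane skeleton gene, was 1.17 against 99.2, 128 and 118 FPKM, and Basp1, a membrane protein of growth cones, was 5.72 against 400, 383 and 296 FPKM. Lgals7, an epithelial galectin gene, and Trap1a, a tumour rejection antigen gene, were 64.2 and 34.3 FPKM in OSKM early cells and listed at 0 in the other 3. Ush1c, a scaffold of hair cell bundles, and Cldn11, a tight junction gene, were 27.5 and 26.5 FPKM in OSKM early cells and listed at 0 in the other 3. Fetub, a liver cystatin gene, was 169 against 2.52, 1.75 and 4.03 FPKM, and Rhox5 was 158 against 2.503, 2.19 and 2.78 FPKM.

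Against OSKM early cells the authors' deposited table called 3509 genes in C2 (1810 higher and 1699 lower), 3444 in C3 (1679 and 1765) and 3402 in C4 (1771 and 1631). By the authors' deposited table, 1235 of 11569 genes were higher and 968 lower in all 3 (independent 36.5 in each direction; simulated 3.20 and 3.25), and part of the excess may come from the shared OSKM group. Fibroblast genes were higher for 21, 17 and 19 of 28 in the authors' deposited table (21, 19 and 20 adjusted over the list alone; adjusted Fisher p 1.2e-09, 1.2e-06 and 3.2e-08). Pluripotency genes were lower for 8, 8 and 10 of 24 in the authors' deposited table (9, 9 and 11 adjusted over the list alone; adjusted Fisher p 0.03, 0.039 and 0.0014), and epithelial genes for 9, 6 and 9 of 17 (10, 7 and 10 adjusted over the list alone; 0.0011, 0.13 and 0.00093). Cell cycle genes were lower for 14, 10 and 7 of 22 in the authors' deposited table (15, 10 and 7 adjusted over the list alone; adjusted Fisher p 7.4e-06, 0.0083 and 0.17). Mki67, a proliferation marker, was 137 FPKM in OSKM early cells and 45 FPKM in C2. Among the delivered factors, Myc was 1482 FPKM in OSKM and 268, 141 and 163 FPKM in C2, C3 and C4 early cells. These contrasts were therefore not of Oct4 against ZFATFs alone.

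Zfp42 was higher in iPS than in early cells across the 4 cocktails by 7.64 on the log2 scale (SE 0.17; limma adjusted p 0.000515). Dppa4 was higher by 7.41 (SE 0.18; limma adjusted p 0.000515) and Dppa5a by 9.38 (SE 0.64; limma adjusted p 0.00219). The largest differences were of Rn45s, a ribosomal RNA precursor, at 12.42 (SE 0.17; limma adjusted p 0.000364), and Kctd19 at 10.47 (SE 0.16; limma adjusted p 0.000364). Both rows were listed at 0 in all 4 early groups, and Rn45s was 3791 to 7114 FPKM in iPS cells, 4813 FPKM in ES cells and listed at 0 in fibroblasts. Kctd19 was 1024 to 1850 FPKM in iPS cells, 0.307 FPKM in ES cells and listed at 0 in fibroblasts. The lower side was led by Ptges2 at -10.81 (SE 1.02; limma adjusted p 0.0033) and Ndufa13 at -9.28 (SE 2.51; limma adjusted p 0.0433), each from 1 of 2 rows of the gene. The other rows showed no such fall. For Ptges2 the other row was 3.66 to 8.80 FPKM in early and 2.70 to 7.35 FPKM in iPS cells. For Ndufa13 it was 36.4 to 55.5 FPKM in early and 44.4 to 59.3 FPKM in iPS cells. A difference in library handling between the stages was not separated from stage. Dnd1, a germ cell RNA-binding protein gene, was higher by 10.15 (SE 0.46; limma adjusted p 0.00117). Its row was 0.0731 to 1.22 FPKM in the 4 early groups used, but 127 FPKM in Empty early cells and 31.6 FPKM in fibroblasts. The same row was 861 to 4181 FPKM in iPS cells and 12162 FPKM in ES cells. Triml2, a tripartite motif gene, was higher by 7.61 (SE 0.20; limma adjusted p 0.00055). Ly6a and Ly6c1, which encode surface antigens of stromal and blood cells, differed by -7.72 (SE 0.30) and -7.66 (SE 0.18), with limma adjusted p of 0.00115 and 0.000515. Thbs1 differed by -7.29 (SE 1.21; limma adjusted p 0.0114), Cxcl1, a neutrophil chemokine gene, by -7.06 (SE 0.91; limma adjusted p 0.00611), and S100a4, a calcium-binding gene of motile cells, by -7.33 (SE 0.63; limma adjusted p 0.00284).

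This stage contrast took the 8 group values as 4 cocktails by 2 stages, with cocktail as a block, and limma called 7394 of 19591 genes (4166 higher and 3228 lower in iPS cells). Of 32 fitted splits of the same 8 values, which include the real one, the others gave at most 4 genes. Each other split mixes the 2 stages, which puts the stage difference into the residual spread. Their low counts therefore do not measure how many calls chance would give. Leaving out a cocktail moved the count: limma called 3031 genes without C4, 3187 without C2, 3560 without C3 and 8607 without OSKM. Pou5f1 was not called (5.19, SE 2.21, limma adjusted p 0.133), with differences of -3.11 in OSKM, 8.14 in C2, 7.41 in C3 and 8.31 in C4. Because Oct4 was delivered to OSKM cells, the value of -3.11 does not separate the construct from the endogenous gene. Of 30 pluripotency genes limma called 29 higher (median 5.17; adjusted Fisher p 2.67e-14), and of 29 fibroblast genes 24 lower (25 adjusted over the list alone; median -3.92; 1.82e-10). Inflammatory genes were lower for 12 of 14 (13 adjusted over the list alone; median -4.24; adjusted Fisher p 9.78e-06), and epithelial genes higher for 16 of 21 and lower for 1 (16 and 2 adjusted over the list alone; median 3.31; 3.11e-05). Glycolysis genes passed no Fisher test (2 higher and 7 lower of 16; adjusted Fisher p 0.206), although their median of -0.44 stood at percentile 0.705 of the matched random lists, with Ldha at -1.92 (SE 0.22; limma adjusted p 0.00451).

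Human EGR1, the transcription factor whose DNA-binding domain was used, was 5.38 FPKM in mock HEK293 cells and 4626 FPKM with 2 fingers of that domain. It was 7474 FPKM with 2 fingers and the segment called ID, and 1813 FPKM with 3 fingers and ID. The constructs carried this domain, so reads of the construct were not separated from those of the endogenous gene. Other genes also had higher values with the 3-finger constructs. ARC, a synaptic activity gene, was 0.837 FPKM in mock, 583 FPKM with 3 fingers and 592 FPKM with 3 fingers and ID. VGF, a neuropeptide precursor gene, was 0.193, 149 and 373 FPKM, and RRAD, a small GTPase gene, was 0.225, 140 and 151 FPKM in the same order. GADD45B, a stress sensor gene, was 22.5, 1201 and 2221 FPKM, and TFPI2, a protease inhibitor gene, was 3.47, 692 and 68.5 FPKM. NAB1, a corepressor of EGR proteins, was 20.5, 68.8 and 128 FPKM, and OLFM2, an olfactomedin gene, was 5.16, 361 and 381 FPKM. CPLX1, a synaptic release gene, was 2.80, 207 and 270 FPKM.

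CHAC1 was 1.10 FPKM in mock, 16 FPKM with 2 fingers and 25.7 FPKM with 2 fingers and ID. DDIT3, a transcription factor of the unfolded protein response, was 22.6, 57.5 and 116 FPKM, and NR1D1, a circadian repressor gene, was 4.73, 37.4 and 32.4 FPKM. TXNIP, a thioredoxin inhibitor gene, was 5.33, 2.39 and 35.1 FPKM, and FOS, an immediate early gene, was 1.22, 1.49 and 15.6 FPKM. HAS3, a hyaluronan synthase gene, was 1.83 FPKM with 3 fingers and 207 FPKM when ID was added, CTSL2, a cathepsin gene, was 17.8 against 970 FPKM, and PLAUR, the urokinase receptor gene, was 13.6 against 194 FPKM. Lower values with 3 fingers were found for NID1, a basement membrane gene (78.8 FPKM in mock, 18.1 with 3 fingers), MAP2, a dendritic microtubule gene (14.8 and 2.29 FPKM), and IGFBP5, a growth factor binding protein gene (18.6 and 2.83 FPKM). GAPDH, the glycolytic reference gene, was 2980 FPKM in mock and 1604 FPKM with 3 fingers.

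Each HEK293 condition had 1 library, so no replicate check was possible and no p-values of this work were computed. By the size rule, 420 genes differed from mock with 2 fingers (267 higher and 153 lower), 1076 with ID added (674 and 402), 1556 with 3 fingers (953 and 603) and 2067 with 3 fingers and ID (1219 and 848). The authors' deposited table called 3, 7, 56 and 101 genes in the same order. Between constructs the size rule counted 773 genes for ID with 2 fingers, 653 for ID with 3 fingers, 1395 for the third finger without ID and 1333 with ID, where the authors' deposited table called 6, 37, 49 and 89. Many of the largest differences belonged to short RNAs listed at 0 in 1 library, so the genes above were named among those at 1 FPKM or more in both libraries or called by the authors, a choice made after the values were seen.

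**Figure D3:**
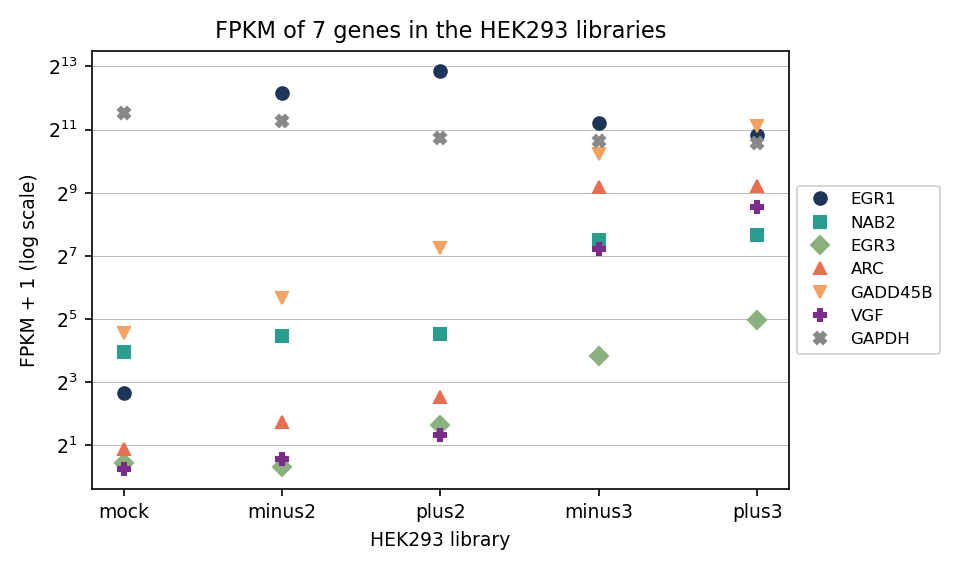
FPKM + 1 of 7 genes in the 5 HEK293 libraries on a log axis, 1 symbol per library. ARC stood at 4.84 FPKM with 2 fingers and ID and at 583 FPKM with 3 fingers.

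Lists in HEK293 cells were placed against 10000 random lists matched on expression. EGR1 targets had medians of 0.12, 0.11, 1.17 and 1.37 against mock for 2 fingers, 2 fingers with ID, 3 fingers and 3 fingers with ID, at percentiles 87.4, 78.5, 100 and 100. Of 27 EGR1 targets, 14 were higher and 1 lower by at least 1 with 3 fingers. The EGR family, which includes the EGR1 row, had medians of 0.50, 0.88, 3.39 and 4.53 over 3, 4, 5 and 5 measured members (0.20, 0.41, 2.54 and 4.53 with members from 0.1 FPKM; 0.53, 1.43, 3.61 and 5.87 with a pseudocount of 0.1), with EGR3, a zinc finger family member, at 0.357 FPKM in mock and 30.3 FPKM with 3 fingers and ID. Immediate early genes had medians of 0.18, 0.91, 1.33 and 1.59, and heat shock and unfolded protein genes 0.58, 0.65, 1.09 and 0.79. Interferon genes had their highest median with 2 fingers and ID (0.54, percentile 99.8), with IFIT1, an antiviral RNA-binding gene, at 3.68 FPKM in mock and 15.9 FPKM. The p53 list had medians of -0.13, -0.46, -0.65 and -0.90, with CDKN1A at 256 FPKM in mock and 83.6 FPKM with 3 fingers and ID. Neuronal genes had medians of -0.06, -1.01, -1.03 and -1.74 over 7, 5, 7 and 5 measured members (0.08, -0.66, -0.91 and -0.74 with members from 0.1 FPKM; -0.09, -1.22, -1.85 and -1.88 with a pseudocount of 0.1), and cholesterol genes -0.23, -0.66, -0.61 and -0.22. With 3 fingers the medians were 0.17 for the cell cycle list (percentile 52.0), 0.25 for pluripotency and 0.00 for kidney epithelial genes. Ubiquitous genes, a reference list, had medians of -0.09, -0.27, -0.15 and -0.23 against mock, at percentiles 61.3, 2.31, 2.97 and 0.79. Low medians of other lists are to be read beside these. For 3 fingers with ID, the cholesterol list stood at percentile 4.92.

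Across 8459 genes the differences for the third finger without and with ID, which share no library, had a Pearson correlation of 0.448. The differences for ID with 2 and with 3 fingers had a correlation of -0.031, and in the authors' deposited table only 6 genes were called for ID with 2 fingers. Of 9721 genes, 251 were higher with the third finger in both settings (672 and 657 in each; 45.4 for independent genes) and 126 lower (466 and 385; 18.5). No floor was set for the lower library in these counts. The largest shared decreases included short RNAs such as RNA5SP149, RNA5S2 and Y_RNA, so the lower count is not of such a finger effect alone. Genes are not independent, so no test was attached to these correlations or to the difference between them.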

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

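Chosen only after the result was seen were the tests of a shared constant, of a normalization shift, of the stem cell move, of the PURO vector, of the ES strain and of the splits of the 8 stage values.

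Between early and iPS cells, 42 genes of the authors' deposited table were higher in iPS cells of C2, C3 and C4 and were called the opposite way in OSKM, and 37 genes were lower in the 3 and opposite in OSKM. Clu, a secreted chaperone gene, differed by -1.34 in OSKM and by 3.48, 4.75 and 4.36 in C2, C3 and C4, and Rhox5 by -1.51 against 5.00, 5.15 and 4.82. Basp1 differed by 3.89 in OSKM and by -2.14, -2.34 and -1.24 in the others, and Pou5f1 by -3.11 in OSKM. Oct4 was delivered to OSKM cells and construct reads were not separated, so the fall of Pou5f1 need not be of the endogenous gene. The OSKM early and iPS groups also differed in Xist (47.0 and 1.62 FPKM) and in Ddx3y (2.30 and 33.4 FPKM). In C2, Ddx3y went the other way, from 23.4 to 4.09 FPKM. Other differences between the groups of a cocktail were therefore not separated from stage. These differences between cocktails are untested. Of the 32 fitted splits of the 8 values only 1, the real one, gave as many as 7394 genes, and the highest other gave 4. The other splits mix the stages, so the stage difference itself lowers their counts.

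The rows of the delivered constructs were read for the groups only. PURO, the puromycin resistance row, was 1764 FPKM in Empty early cells and 313, 1205 and 390 FPKM in C2, C3 and C4 early cells. The joined row of PURO and ZFATF2 was 81.7, 411 and 195 FPKM in C2, C3 and C4 early cells. ZFATF1 was 25.3 FPKM in C3, ZFATF3 was 36.2 FPKM in C2, ZFATF4 was 25.6 FPKM in C3 and ZFATF5 was 6.58 FPKM in C4 early cells. All 6 rows were listed at 0 in ES cells and in all 4 kinds of iPS cells. No difference between groups was tested for these rows.

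OSKM early cells stood apart from Empty early cells in 3412 genes of the authors' deposited table. Chromosomes X and Y held 4.02% of these genes (3.41% to 4.73%), against 3.19% of genes tested. So few tested genes lie there that a high share was out of reach, so this could not decide on the sex of the cells. Xist was higher and Ddx3y lower in OSKM than in Empty early cells. Any single constant left at least 54.7% of them 1 or more away from it on the log2 scale, which argues against a shift of all values as the main source. The difference correlated with that of ES cells from fibroblasts, which shares no group with it, at 0.525, and a move towards the stem cell profile may be part of the pattern. The vector stays open, because OSKM early cells also had a PURO value of 0.51 FPKM, the lowest of the early groups. Delivered factors other than Oct4 also differed: Myc was 1482 FPKM and Klf4 419 FPKM in OSKM early cells, above their values in Empty. This contrast was therefore not of Oct4 alone.

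For the 474 genes higher in every kind of iPS cell than in ES cells, 3 possible sources were looked at. Others were not, among them the tamoxifen that the labels give for iPS cells and not for ES cells. RNA from fibroblasts or feeder cells reached the excess of 0% of them, at a median allowed share of 0.126% to 0.257%. The 20 fibroblast genes behind this share left out any gene higher in every kind of iPS cell. RNA carried over would raise such genes, so this could not decide on that source. No feeder cells were measured. Expression kept from fibroblasts stays open: 28.1% of them were higher in fibroblasts than in ES cells, against 18.5% of genes tested. The strain and history of the ES line also stay open, because Hprt, at 0.957 FPKM in ES cells only, could reflect the line itself, as some lines of the E14 family lack this gene.

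Named loci with an isolated very high value numbered 37. Of these, 32.4% overlapped an annotated gene with under 200 exonic bases, against 14.8% of the other named loci (Fisher exact p 0.00809) and 20.7% of those of like width. The difference from loci of like width was not tested, so short features stay open as a source. A constant shared by unrelated loci of a group stays open, because 18.9% of the values lay within 0.1% of another of the same group and 13.5% within 0.1% of one of another group.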

How the results depend on the processing

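All tests of unnamed loci, of isolated loci and of a floor of 1 FPKM in both HEK293 libraries were chosen only after the result was seen. No paired analysis was possible because each mouse group entered with 1 value and no column carries a replicate number, and the only block was cocktail in the stage contrast. For the same reason a pseudocount, quantile normalization, fits of 2 groups alone and leaving out replicates could not be run for the gene counts of the 20 contrasts. A pseudocount was run for their list medians. A count was labelled the same when it stayed within 1.5 times the reported one. The cause of each move was not tested unless stated. The larger of the higher and lower counts changed side under 15 settings of the 20 contrasts and 1 of the HEK293 contrasts. It did so from 1049 higher and 939 lower to 407 and 468 for OSKM iPS against ES cells with a difference of at least 1, from 395 and 362 to 115 and 133 for C3 against OSKM iPS cells with correction within the contrast, and from 1570 and 1842 to 2250 and 2157 for OSKM against Empty early cells with unnamed loci.

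Against ES cells, the deposited calls at a q-value of 0.01 fell to 1178 in OSKM, 1220 in C2, 1040 in C3 and 1452 in C4 iPS cells, and with a difference of at least 1 to 875, 861, 838 and 1023. Against OSKM iPS cells, correction within the contrast gave 163 genes in C2, 248 in C3 and 182 in C4, a q-value of 0.01 gave 239, 332 and 251, and a difference of at least 1 gave 157, 243 and 166. Between Empty early cells and fibroblasts, a difference of at least 1 left 1676 genes. Against Empty early cells, correction within the contrast gave 485 genes in C2, 611 in C3 and 592 in C4, a q-value of 0.01 gave 485, 565 and 566, and a difference of at least 1 gave 482, 521 and 549. With unnamed loci C2 early cells had 1374 loci. A floor of 1 FPKM gave identical counts in all 20 contrasts and so tested nothing. Removal of isolated loci changed them by a few genes (6355 to 6347 for ES cells against fibroblasts, 511 to 503 for C2 against OSKM iPS cells).

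The stage count ranged from 3031 genes without C4 to 8607 without OSKM. Leaving out C2 (3187 genes), C3 (3560 genes) or C4 was labelled as moved. All other settings were labelled the same, among them 8457 genes without the block, against 7394 with it. Without isolated loci the axis positions of iPS cells were 89.6% for C2, 88.1% for C3, 87.0% for C4 and 87.4% for OSKM, and across settings groups moved by -1.21 to 2.86 points.

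In HEK293 cells, 1 FPKM in the higher library gave 708 genes for 2 fingers against mock, 1175 for ID with 2 fingers and 1012 for ID with 3 fingers. The authors' deposited calls were 3, 7, 56 and 101 against mock, and 6, 37, 49 and 89 between constructs. A floor of 1 FPKM in both libraries lowered the counts within those 1.5 times, from 420 to 286 for 2 fingers against mock, from 773 to 606 for ID with 2 fingers and from 653 to 496 for ID with 3 fingers. A subtracted median kept all 8 counts within them. The list medians of the mouse and HEK293 contrasts were counted together, 434 of them from mouse contrasts. Of these medians of both species, 125 moved by more than 0.5 with a pseudocount of 0.1 and 405 did not. With members from 0.1 FPKM 81 moved and 449 did not. Their sign changed for 3 and 46 medians. The neuronal medians against mock became 0.08, -0.66, -0.91 and -0.74 with members from 0.1 FPKM.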

Other observations

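Zscan4f, a marker of the rare 2-cell-like state of stem cell cultures, was 3.37 FPKM in ES cells and 2.11, 0.359, 0.13 and 0.531 FPKM in OSKM, C2, C3 and C4 iPS cells. Phlda2, an imprinted growth inhibitor of the placenta, was 41.5 FPKM in ES cells and 9.38, 3.58, 6.03 and 4.86 FPKM in the same iPS groups. Krt8, a simple epithelial keratin gene, was 81.1 FPKM in OSKM early cells and 12.2 FPKM in OSKM iPS cells. Tfap2a, an ectoderm and trophoblast regulator, was 21.2 FPKM in OSKM early cells and 0.451 FPKM in OSKM iPS cells. Zic2, a zinc finger gene of the early epiblast, was 33.3 FPKM in OSKM early cells and 17.6 FPKM in OSKM iPS cells. Laptm5, a lysosomal protein of blood cells, was 31.2 FPKM in OSKM early cells and listed at 0 in Empty early cells.

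Nes, an intermediate filament gene of progenitors, was 1.48 FPKM in Empty early cells and 21.2, 2.86 and 13.6 FPKM in C2, C3 and C4 early cells. Peg10, a retrotransposon-derived imprinted gene, was 0.961 FPKM in Empty early cells and 33.6 FPKM in C2. B2m, the light chain of class I molecules, was 126 FPKM in fibroblasts, 3.09 FPKM in ES cells and 46.4 FPKM in Empty early cells. Uty, a Y-linked demethylase gene, was listed at 0 in fibroblasts and stood at 22.3, 40.4, 55.4 and 16.1 FPKM in OSKM, C2, C3 and C4 iPS cells. Its row was also listed at 0 in C4 and OSKM early cells. There Ddx3y was 19.2 and 2.30 FPKM, and Eif2s3y, another Y-linked gene, was 5.44 and 6.18 FPKM. A listing of Uty at 0 therefore does not show that Y-linked expression was absent.

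Between kinds of iPS cells the authors' deposited table called 440 genes for C2 and C3, 163 for C2 and C4, and 492 for C3 and C4. Between early cells the authors' deposited table called 728, 820 and 633 in the same order. Between iPS and early cells of a cocktail the authors' deposited table called 4493 genes in OSKM, 5779 in C2, 5443 in C3 and 5488 in C4. In HEK293 cells the Pearson correlation with mock across genes at 5 FPKM or more in both libraries was 0.971 for 2 fingers, 0.936 with ID, 0.918 for 3 fingers and 0.888 with ID. Among ES and fibroblast differences of at least 5 on the log2 scale, 33.3% of 66 genes were called where the lower group was listed at 0, 4.41% of 68 between 0 and 0.1 FPKM, 63.9% of 133 above 0.1 and up to 1 FPKM, and 89.5% of 76 above 1 FPKM. Of unnamed loci up to 50, 51 to 100, over 100 to 1000 and over 1000 bases wide, 83.3%, 68.4%, 0.202% and 2.01% exceeded 10000 FPKM in a group.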
